A study of Homo sapiens with 9 samples.

How the data were processed

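RNA from 9 cultured human lung MSC colonies, each at passage 4, was sequenced as 1 unstranded library per colony. Per the labels, lung tissue was digested with dispase, collagenase and DNase, and cells were grown in alpha MEM with 20% fetal bovine serum. The labels put every colony in a single group and do not say whether colonies came from separate donors. The spread between them therefore covers differences between these cultures and libraries, and can include differences between donors. Per the labels, the authors trimmed reads with cutadapt 5.0 and Trimmomatic 0.38, checked them with FastQC 0.11.9, aligned them with STAR to GRCh38.p14 and analysed them with edgeR 4.0. The read counter and the annotation release were not given in the sources used here.

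The deposited table held 34481 genes, of which 1181 had no count in any colony and 33300 at least 1, and 8940 had no gene name. Per the file headers, 9 columns held raw counts per gene. Deposited RPKM values were counts per kilobase of a length column scaled by an effective library size. That length appears to sum the exons of all transcripts (33157 bases and 151 exons for EYA4), so RPKM was not compared between genes and served as an alternative only. The authors gave log2 fold changes, log2 mean CPM, the likelihood ratio as a score per gene, a p-value and its FDR, which is the Benjamini-Hochberg adjustment over all genes. The table name states RUV and upper-quartile normalization, and the number of RUV factors was not given in the sources used here. A further 9 deposited columns of TMM values were not used.

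Counts were scaled to CPM with TMM factors from edgeR 4.0.16 in R 4.3.3, between 0.826 in colony D and 1.22 in colony S. Levels were compared as log2(CPM + 1) over the 13152 genes with a mean of at least 1 CPM. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and limma 3.58.1 were also used. Total counts ran from 15280226 in colony T to 22310590 in colony S, and a count of 0 allowed 0.11 to 0.219 CPM.

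The group comparison was not refitted, because the labels do not state the members of its groups and groups were not inferred from the values. Genes at an FDR under 0.05 were counted by sign. The 34 gene lists, the tests and the rule for named genes were fixed before the data were examined. For each list, the median log2 fold change of the authors was compared, two-sided, with 10000 random lists of the same size drawn within 20 bins of mean expression, with Benjamini-Hochberg adjustment over the lists. The smallest p this can give is 0.0002. The alternative test was cameraPR of limma on the signed root of the likelihood ratio, with an inter-gene correlation estimated over the colonies or, added after seeing the data, preset at 0.01. Negative estimates were set to 0. Members past an FDR of 0.05 were counted over all genes and adjusted over the list alone.

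Between colonies, Pearson correlations across genes were computed for each pair, and genes with an SD above 1 on the log2 scale were counted as variable. The median SD of each list was compared with random lists in the same way. A list score was the mean z-score of its genes, leaving out genes shared by both lists of a pair, and 12 pairs chosen beforehand were correlated by exact permutation over all 362880 pairings, two-sided. A pooled correlation was to be given only if no gap on the first principal component exceeded 50% of its range. Exons of named genes were compared, on either strand, with those of other genes in a GENCODE annotation chosen for this step. The release behind the deposited counts is not known, so overlaps in it can differ. The 7 of 143 named genes with over 20% of exon bases shared with another gene were ANKRD37, EML5, HOXD4, MCM2, PLAU, RRM2 and TYMS.

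Named genes were the 15 with the largest positive and the 15 with the largest negative fold change among those at an FDR under 0.05 with a mean of at least 1 CPM and an ordinary gene symbol. Added to them were up to 4 members of each list with the smallest p at an FDR under 0.05, the 9 MSC surface markers, the most abundant markers of other cell types and the 10 most variable genes. Sex-linked marker genes, HLA class II genes and genes commonly deleted in people were not named. Alternatives covered the FDR, a fold-change minimum, the filter on low levels, the pseudocount, the scaling, rank correlation, the mean in place of the median, and leaving out each colony in turn. The deposited RPKM, the checks on the first principal component and the omission of genes resting on 1 colony were added after seeing the data.

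The methods were tested on simulated data with the depth and mean gene levels of these libraries, an assumed dispersion of 0.05 and independent genes. Real genes of a list are correlated, which these data did not include. Genes changed 4-fold passed the SD limit in 53.8% of cases and genes changed 8-fold in 93.8%, while none passed at 2-fold. Of 6 lists in which every member was raised 2-fold, drawn from the same changed genes, 100% were found. Lists with part of their members changed were not simulated. Of 100 unshifted lists, 5.00% passed at an unadjusted p under 0.05. Strong correlations were found in 98.0% of cases, and 4.50% of unrelated pairs passed.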

Results

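The series profiled gene expression in mesenchymal stem cells (MSC) grown from human lung. MSC are plastic-adherent stromal cells, and each colony here was a cell culture expanded to passage 4. Total RNA of 9 colonies, named D, W, P, M, K, I, T, G and S, was sequenced as 1 unstranded library each. The labels placed all 9 colonies in 1 group of primary lung MSC and did not say which colony belonged to which subpopulation. Gene counts totalled 16609194 in D, 16797483 in W, 18154014 in P, 16767789 in M, 19794466 in K, 16001354 in I, 15280226 in T, 17178688 in G and 22310590 in S. The 10 most abundant genes held between 7.87% of the counts in colony G and 19.8% in colony M. Mitochondrially encoded genes held between 1.83% in colony I and 2.95% in colony K. A count of 0 allowed up to 3 counts, which is between 0.11 CPM (counts normalised to library size with TMM factors) in colony S and 0.219 CPM in colony D, for counting error only.

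The study asked how subpopulations of lung MSC differ in gene expression, and its design text stated that the grouping came from hierarchical clustering. The authors' deposited table held 1 comparison between such groups, with a log2 fold change, a p-value and a false discovery rate (FDR) per gene. Which colonies formed each group, and which group a positive value favours, are not stated in the labels or the table, and groups were not inferred from the values. Fold changes are therefore given by sign, with CPM per colony, the range or the mean ± SD over the 9 colonies beside part of them. Because the groups were formed by clustering the same libraries, the authors' p-values are not independent evidence that the groups differ. Of 34481 genes in the authors' deposited table, 2533 had an FDR under 0.05, 1380 with a positive and 1153 with a negative fold change. Among genes with a mean of at least 1 CPM, 900 were positive and 670 negative in the authors' deposited table. The median fold change over the 13152 genes of that level was 0.02 on the log2 scale in the authors' deposited table.

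Of 34 gene lists fixed before the data were examined, 18 had a median fold change above that of random lists of like expression, and 1, the cell cycle list, had a median below it. The other 15 lists did not pass that test. By another test, limma cameraPR, 14 of the 19 calls were kept at a preset inter-gene correlation of 0.01, chosen after the data were seen. With a correlation estimated over the colonies, that test kept 1 call, that of the interstitial collagens, and 18 were lost. Of the 19 lists that passed, 13 had an unadjusted p under 0.05 with the estimated correlation. Median, mean and that test differed in sign for the epithelial, Schwann, peribronchial, lung transcription factor, anterior HOX and WNT lists, none of which passed. The estimated correlation was 0 for 2 of the 19 lists, the progenitor markers and growth factors, whose calls were lost with the change of test itself. It was estimated with no group term, since the groups are not stated, so a difference between the groups raises it. Below, the adjusted p against random lists and that of cameraPR with the estimated correlation are given for each list.

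**Figure D1:**
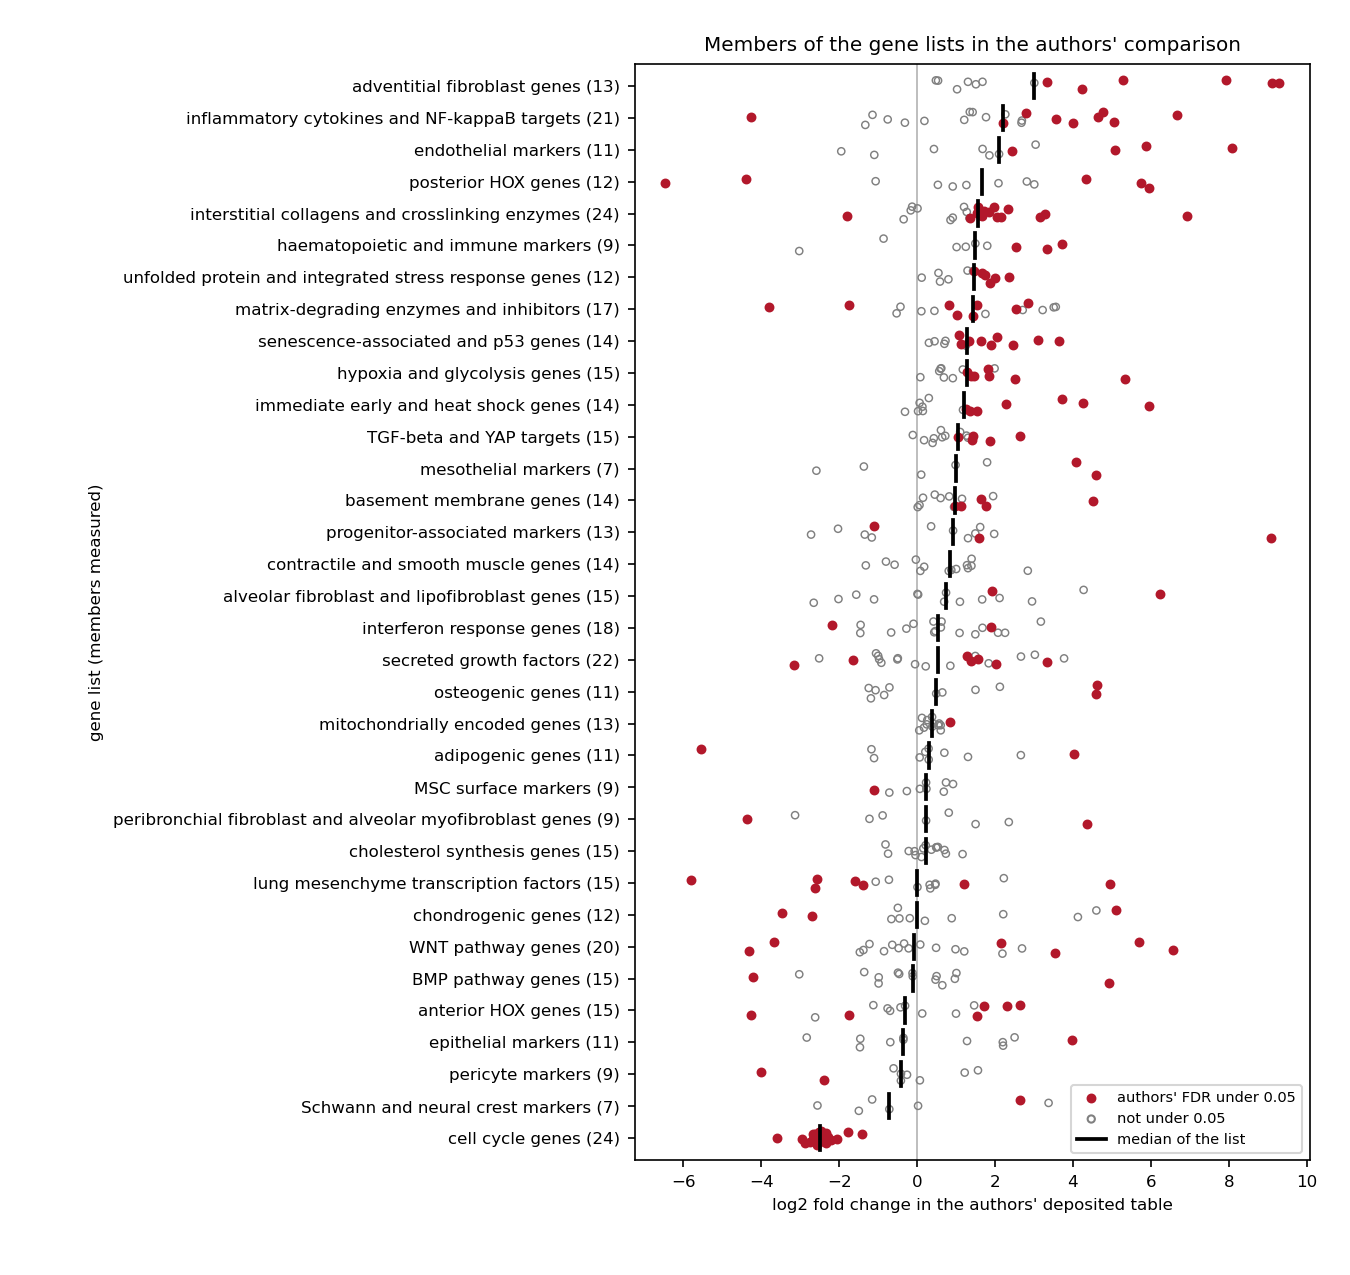
Each point is 1 gene of a list, placed by its log2 fold change in the authors' deposited table. Lists are ordered by their median (black bar), which runs from -2.49 for the cell cycle genes to 3.01 for the adventitial fibroblast genes, and filled points had an FDR under 0.05.

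Genes of the fibrous extracellular matrix were mostly positive, and theirs was the list whose call held against random lists and with the estimated correlation. That correlation was 0.36 for this list and 0.97 for the cell cycle list, and a difference between the groups raises it. Both lists kept their calls at the preset correlation. In the authors' deposited table, 14 of 24 interstitial collagen and crosslinking genes were positive at an FDR under 0.05 and 1 was negative (18 positive and 1 negative adjusted over the list alone). As a list they had a median of 1.55 in the authors' deposited table (adjusted p = 0.000567 against random lists, adjusted p = 0.0436 with an estimated correlation). The 4 members with the smallest p in the authors' deposited table were POSTN (log2 fold change 6.93, FDR = 7.27e-14), FN1 (log2 fold change 2.32, FDR = 3.61e-11), COL3A1 (log2 fold change 3.28, FDR = 6.91e-08) and LOX (log2 fold change 3.16, FDR = 1.25e-07). POSTN encodes periostin, a collagen-binding matricellular protein, FN1 encodes fibronectin, COL3A1 a chain of fibrillar collagen, and LOX the lysyl oxidase that crosslinks collagen and elastin. POSTN (ENSG00000133110.15, chromosome 13, 37562585 to 37598768, GRCh38.p14) ranged over 11.0 to 10048 CPM, with a mean of 3131 ± 3530.4 CPM (SD, n = 9). Its level was 3547 in D, 4214 in W, 3552 in P, 6634 in M, 10048 in K, 104 in I, 54.4 in T, 11.0 in G and 15.2 in S, all in CPM. FN1 averaged 29420.0 ± 19889.6 CPM, COL3A1 5290.2 ± 5533 CPM and LOX 1239 ± 1202 CPM (SD, n = 9 each). The 1 negative member in the authors' deposited table, named after its values were seen, was elastin (ELN, -1.81, FDR = 0.0303), at 236 ± 225 CPM (SD, n = 9). The share of counts in the 10 most abundant genes also varied between colonies: 18.8% in D, 15.6% in W, 15.8% in P, 19.8% in M, 16.7% in K, 9.03% in I, 10.8% in T, 7.87% in G and 8.08% in S.

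Other matrix lists had positive medians too. For the basement membrane list, the authors' deposited table had 5 of 14 genes positive and 0 negative (9 positive and 0 negative adjusted over the list alone), among them LAMA2 (1.76) and LAMC1 (1.12), chains of laminin, HSPG2 (0.98), which encodes perlecan, COL4A5 (4.51), a chain of type IV collagen, and another such chain, COL4A1 (1.64), named after its values were seen. Its median in the authors' deposited table was 0.96 (adjusted p = 0.000971 against random lists, adjusted p = 0.117 with an estimated correlation). COL4A5 was at 0 in D, 231 in W, 250.2 in P, 224 in M, 137 in K, 4.62 in I, 4.11 in T, 20.8 in G and 0.0366 in S, all in CPM. Among matrix-degrading enzymes and their inhibitors, 6 of 17 were positive and 2 negative in the authors' deposited table (11 positive and 2 negative adjusted over the list alone). Over the whole list the median in the authors' deposited table was 1.43 (adjusted p = 0.000567 against random lists, adjusted p = 0.0738 with an estimated correlation). The metalloproteinase inhibitor TIMP1 (2.54) and the proteases MMP2 (1.54) and ADAMTS1 (1.43) were positive, while PLAU (-3.79), the urokinase gene, and TIMP4 (-1.75), named after its values were seen, were negative in the authors' deposited table. Part of PLAU's exons overlap those of a gene on the opposite strand, so its unstranded counts can include reads of both. Of the TGF-beta and YAP targets, 5 of 15 were positive and 0 negative in the authors' deposited table (5 positive and 0 negative adjusted over the list alone), including CCN2 (1.86), ANKRD1 (2.65), PMEPA1 (1.42) and SKIL (1.05), the last named after its values were seen. The list median was 1.05 in the authors' deposited table (adjusted p = 0.000567 against random lists, adjusted p = 0.0948 with an estimated correlation). CCN2 averaged 1776 ± 1212 CPM (SD, n = 9).

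All 24 cell cycle genes were negative at an FDR under 0.05 in the authors' deposited table (0 positive and 24 negative adjusted over the list alone). As a list they had a median of -2.49 in the authors' deposited table (adjusted p = 0.000567 against random lists, adjusted p = 0.0738 with an estimated correlation). The 4 with the smallest p in the authors' deposited table were RRM2 (log2 fold change -3.59, FDR = 4.12e-05), TYMS (log2 fold change -2.51, FDR = 8.78e-05), MCM2 (log2 fold change -2.33, FDR = 9.90e-05) and MCM6 (log2 fold change -1.78, FDR = 0.000271). RRM2 and TYMS supply deoxynucleotides, and the MCM proteins form the replicative helicase. RRM2 stood at 5.54 in D, 45.3 in W, 5.53 in P, 14.8 in M, 5.42 in K, 346 in I, 97.9 in T, 176 in G and 121 in S, all in CPM, with a mean of 90.8 ± 113 CPM (SD, n = 9). MCM2 averaged 35.3 ± 31.8 CPM and MCM6 50.5 ± 37.4 CPM (SD, n = 9 each). The exons of TYMS, RRM2 and MCM2 overlap those of neighbouring genes by 39.1%, 20.2% and 22.7% of their bases in the annotation compared. Part of their counts can therefore be ambiguous.

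The list of senescence-associated and p53-regulated genes had the opposite sign. In the authors' deposited table, 9 of its 14 genes were positive and 0 negative (12 positive and 0 negative adjusted over the list alone). Its median in the authors' deposited table was 1.29 (adjusted p = 0.000567 against random lists, adjusted p = 0.0738 with an estimated correlation). Members named were IGFBP7 (log2 fold change 1.89, FDR = 5.91e-06), CDKN1A (log2 fold change 1.64, FDR = 0.000321), IGFBP5 (log2 fold change 3.65, FDR = 0.00104) and ZMAT3 (log2 fold change 1.32, FDR = 0.00114), all from the authors' deposited table. CDKN1A encodes p21, an inhibitor of cyclin-dependent kinases, and IGFBP5 and IGFBP7 encode secreted proteins that bind insulin-like growth factors. CDKN1A ranged over 357 to 2018 CPM and averaged 1017 ± 606 CPM (SD, n = 9). IGFBP5 ranged from 59.5 CPM in W to 4014 CPM in P.

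List scores, each the mean z-score of a list's genes, were then set against each other over the 9 colonies. Of 12 pairs of lists, 2 had a Pearson correlation past the threshold after adjustment. The cell cycle score fell as the collagen score rose, with r = -0.96 (n = 9, exact two-sided permutation p = 0.000400, adjusted p = 0.00240) and rho = -0.95 (exact permutation p = 0.000353, adjusted p = 0.00423). Without colonies D and P, the 2 farthest from the median cell cycle score, r was -0.95 (n = 7, exact permutation p = 0.000992). The cell cycle and senescence scores had r = -0.95 (n = 9, exact permutation p = 0.000292, adjusted p = 0.00240), and r = -0.97 without the same 2 colonies (n = 7, exact permutation p = 0.000794). Their rank correlation was rho = -0.80 (n = 9, exact permutation p = 0.0138), which did not pass after adjustment (adjusted p = 0.0830). The contractile score was not related to the collagen score at this number of colonies (r = 0.27, n = 9, exact permutation p = 0.468, adjusted p = 0.562). The largest gap between neighbouring colonies on the first principal component was 43.5% of its range, under the limit of 50% set beforehand for a pooled correlation. The colonies still clustered into a set of 5 and a set of 4, which are not groups of the labels and hold fewer than the 6 colonies needed for a correlation here, so no relation was computed within a set, and the pooled values do not separate a trend from a difference between sets.

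**Figure D2:**
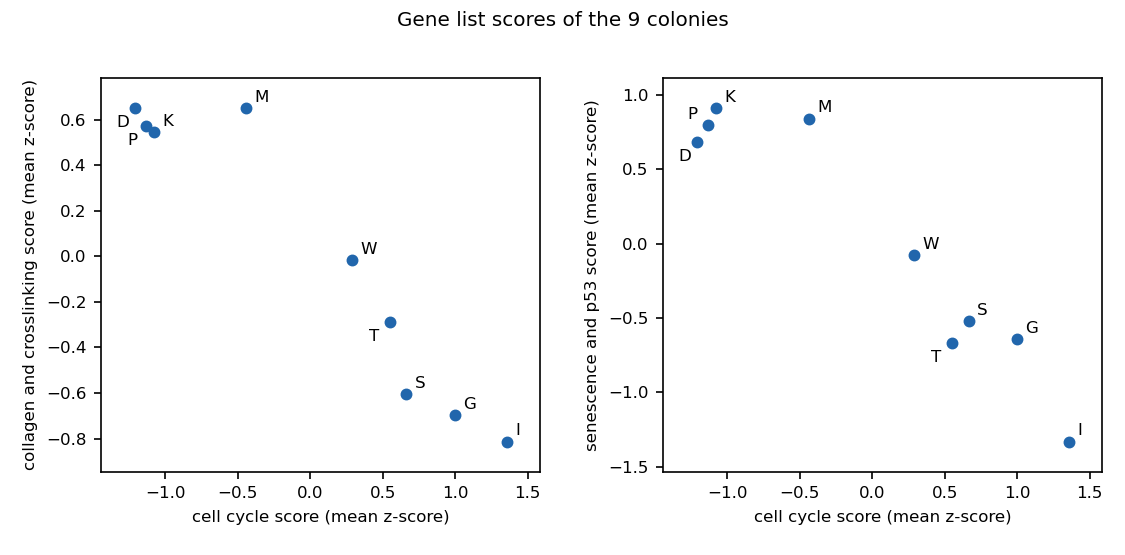
The cell cycle score of each colony (mean z-score over 24 genes) is plotted against its collagen and crosslinking score (24 genes, left) and its senescence and p53 score (14 genes, right), 1 point per colony with its letter. Colony I has the highest cell cycle score (1.36) and the lowest collagen score (-0.81), and colony D the lowest cell cycle score (-1.21).

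Adventitial fibroblast genes, which mark stromal cells of vessel and airway sheaths, had the highest median of the 34 lists. In the authors' deposited table, 6 of 13 were positive and 0 negative (7 positive and 0 negative adjusted over the list alone). Over the whole list the median in the authors' deposited table was 3.01 (adjusted p = 0.000567 against random lists, adjusted p = 0.0812 with an estimated correlation). That median was the value of SLPI, which had an FDR of 0.162. Of the 13 members, 12 had a mean of at least 1 CPM. The named members in the authors' deposited table were MFAP5 (7.93), a microfibril protein, DPP4 (4.23), a surface peptidase, SCARA5 (9.29), a scavenger receptor, C3 (5.29), complement component 3, CD34 (3.34) and PI16 (9.10). MFAP5 was at 72.9 in D, 349 in W, 108 in P, 354 in M, 462 in K, 3.15 in I, 1.19 in T, 0 in G and 0.0732 in S, all in CPM. DPP4 averaged 105 ± 129 CPM (SD, n = 9). PI16, SCARA5 and C3, which are 3 of the 6, rested on colony K, which held 98.2%, 97.3% and 82.3% of their CPM summed over the colonies.

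Inflammatory cytokines and NF-kappaB targets had a positive median, with 8 of 21 positive and 1 negative in the authors' deposited table (11 positive and 1 negative adjusted over the list alone). The list median was 2.22 in the authors' deposited table (adjusted p = 0.000567 against random lists, adjusted p = 0.0643 with an estimated correlation). PTGS2, the inducible prostaglandin synthase (log2 fold change 4.63, FDR = 1.18e-08), TNFAIP3, a feedback inhibitor of NF-kappaB (2.22, FDR = 9.09e-06), and IL1A (6.66, FDR = 9.93e-06) were positive in the authors' deposited table. The chemokine CXCL12 had the opposite sign in the authors' deposited table (-4.26, FDR = 1.49e-05). CXCL12 was at 11.2 in D, 4.54 in W, 86.7 in P, 9.25 in M, 54.3 in K, 307 in I, 1048 in T, 496 in G and 685 in S, all in CPM. TNFAIP3 averaged 43.8 ± 30.4 CPM and PTGS2 5.57 ± 6.35 CPM (SD, n = 9 each). IL1A was low throughout, at 0 to 3.41 CPM.

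Lists of stress, hypoxia and immediate early genes had positive medians. Of 12 unfolded protein and integrated stress response genes, 6 were positive and 0 negative in the authors' deposited table (8 positive and 0 negative adjusted over the list alone), with CHAC1 (2.37), DNAJB9 (2.01), SESN2 (1.88) and HERPUD1 (1.47) named. As a list they had a median of 1.45 in the authors' deposited table (adjusted p = 0.000567 against random lists, adjusted p = 0.0738 with an estimated correlation). Hypoxia and glycolysis genes had 7 of 15 positive and 0 negative in the authors' deposited table (10 positive and 0 negative adjusted over the list alone), including HK2 (2.51), a hexokinase, EGLN3 (5.34), an oxygen-sensing prolyl hydroxylase, and NDRG1 (1.85). Its median in the authors' deposited table was 1.27 (adjusted p = 0.000567 against random lists, adjusted p = 0.131 with an estimated correlation). HK2 averaged 68.9 ± 56.9 CPM (SD, n = 9), while EGLN3 was at 0 to 4.45 CPM. Immediate early and heat shock genes had 7 of 14 positive and 0 negative in the authors' deposited table (7 positive and 0 negative adjusted over the list alone), and the transcription factor genes EGR1 (2.28), EGR2 (5.96), EGR3 (4.26) and FOS (3.73) were the ones named. Over the whole list the median in the authors' deposited table was 1.21 (adjusted p = 0.000567 against random lists, adjusted p = 0.0738 with an estimated correlation). None of the heat shock members had an FDR under 0.05 in the authors' deposited table. They were HSPA1A (0.02), HSPA1B (0.07), DNAJB1 (0.14) and HSPH1 (-0.31), named after their values were seen. EGR1 averaged 49.2 ± 55.4 CPM (SD, n = 9), and EGR2 stayed at 0 to 0.802 CPM.

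Transcription factors that pattern the lung mesenchyme split by sign. In the authors' deposited table, 5 of 15 were negative and 2 positive (3 positive and 7 negative adjusted over the list alone). The negative ones in the authors' deposited table were TBX4 (log2 fold change -5.81, FDR = 1.32e-06), FOXF2 (log2 fold change -2.57, FDR = 3.05e-09), TBX2 (log2 fold change -2.61, FDR = 0.000604) and TBX5 (log2 fold change -1.39, FDR = 0.00439), together with TBX3 (-1.59). The positive ones in the authors' deposited table were BARX1 (4.96) and GLI1 (1.20); these and TBX3 were named after their values were seen. The list as a whole did not stand apart in the authors' deposited table (median 0.01, adjusted p = 0.858 against random lists, adjusted p = 0.0850 with an estimated correlation). With genes under a mean of 1 CPM left out, its median was -0.36 in the authors' deposited table and it passed (adjusted p = 0.0176 against random lists). TBX4 (ENSG00000121075.11, chromosome 17, 61452422 to 61485110, GRCh38.p14) was at 1.46 in D, 0 in W, 3.02 in P, 0.139 in M, 0.210 in K, 25.9 in I, 47.0 in T, 62.8 in G and 82.3 in S, all in CPM. TBX2, also on chromosome 17, averaged 131 ± 116 CPM, FOXF2 34.6 ± 30.3 CPM and TBX5 28.5 ± 15.1 CPM (SD, n = 9 each).

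HOX genes, which record position along the body axis, went both ways. Of 12 posterior HOX genes measured, 3 were positive and 2 negative in the authors' deposited table (4 positive and 2 negative adjusted over the list alone). The positive ones in the authors' deposited table were neighbours in the HOXC cluster on chromosome 12, HOXC9 (log2 fold change 5.96, FDR = 1.10e-14), HOXC8 (log2 fold change 5.75, FDR = 7.62e-07) and HOXC6 (log2 fold change 4.33, FDR = 5.00e-08). The negative ones in the authors' deposited table were HOXD8 (-6.47) and HOXB8 (-4.38), the latter named after its values were seen, and HOXD8 had counts in colony S alone (2.42 CPM). The list median was 1.68 in the authors' deposited table (adjusted p = 0.000567 against random lists, adjusted p = 0.0738 with an estimated correlation). The lists do not part strictly by position: HOXC6 and HOXA7 were in the posterior list, HOXB6 and HOXB7 in the anterior list. The median is therefore not a shift of posterior genes as a class. In the authors' deposited table all measured HOXC members were positive, and all HOXB members but HOXB9 (2.82) were negative, as seen afterwards. HOXC8 was at 9.26 in D, 16.9 in W, 35.3 in P, 31.0 in M, 57.3 in K, 0.282 in I, 0.357 in T, 1.57 in G and 0 in S, all in CPM. Of 15 anterior HOX genes, 4 were positive and 2 negative in the authors' deposited table (5 positive and 3 negative adjusted over the list alone), among them HOXC4 (2.32), HOXC5 (2.64), HOXA3 (1.55), HOXB6 (-1.76) and HOXD4 (-4.26), of which HOXC5 and HOXA3 were named after their values were seen. The anterior list did not pass in the authors' deposited table (median -0.31, adjusted p = 0.208 against random lists, adjusted p = 0.80 with an estimated correlation). In the annotation compared, HOXC4 and HOXC6 share exons, and HOXD4 overlaps another gene over 80.5% of its exon bases. Their counts may therefore not be fully separated.

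**Figure D3:**
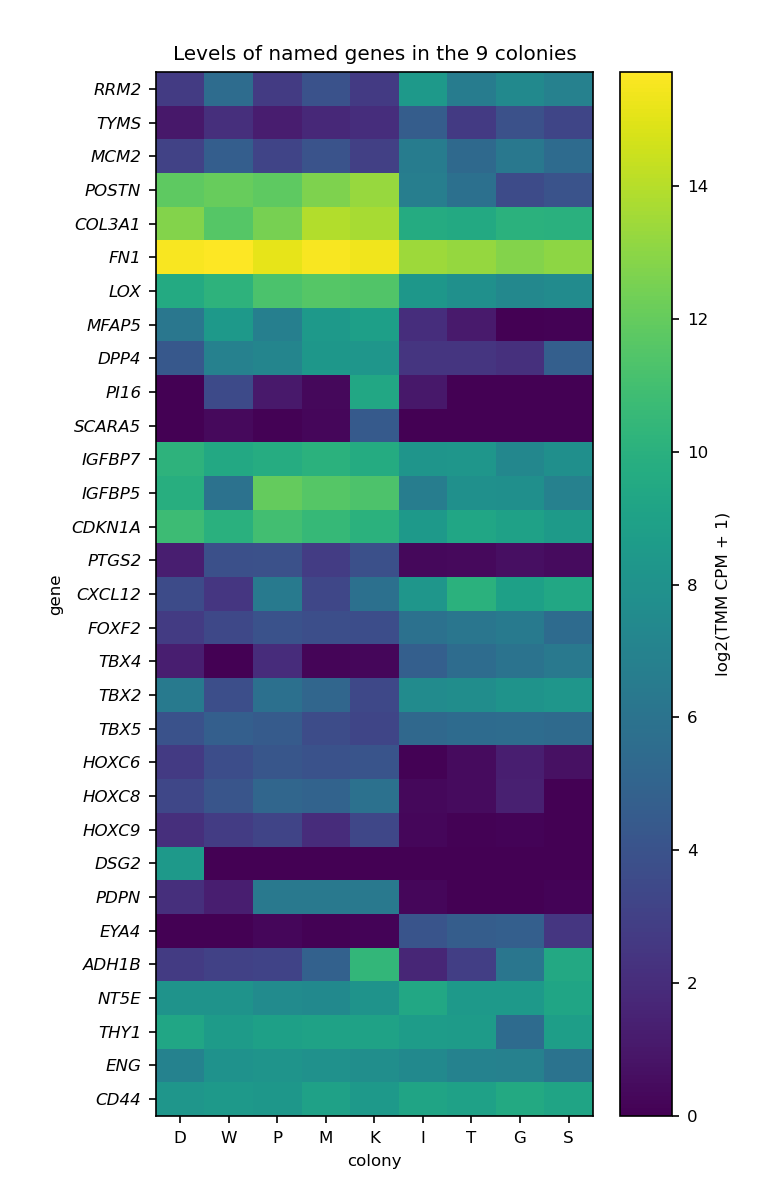
Rows are named genes and columns the 9 colonies; colour gives log2(CPM + 1). FN1 is the most abundant gene shown, at 7215 to 53823 CPM, and DSG2 is seen in colony D alone (356 CPM).

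All 9 MSC surface markers were detected in every colony. Their means were 353 ± 179 CPM for NT5E, 428 ± 165 CPM for THY1, 179 ± 76.0 CPM for ENG, 475 ± 152 CPM for CD44, 2598 ± 804 CPM for ITGB1, 419 ± 154 CPM for ALCAM, 859 ± 255 CPM for ITGA5, 171 ± 77.8 CPM for PDGFRA and 323 ± 159 CPM for PDGFRB (SD, n = 9 each). NT5E, which encodes CD73, was the 1 of 9 with an FDR under 0.05 in the authors' deposited table (log2 fold change -1.10, FDR = 0.0209; 2 positive and 2 negative adjusted over the list alone), and the list did not stand apart (median 0.23, adjusted p = 0.763 against random lists, adjusted p = 0.822 with an estimated correlation). THY1, which encodes CD90, was at 43.4 CPM in colony G, and the next lowest colony had 388 CPM. Among 13 progenitor-associated markers, 2 were positive and 1 negative in the authors' deposited table (3 positive and 4 negative adjusted over the list alone): PDPN (9.08), which encodes podoplanin, ITGAV (1.59), and NT5E again. As a list they had a median of 0.92 in the authors' deposited table (adjusted p = 0.00272 against random lists, adjusted p = 0.336 with an estimated correlation). With genes under a mean of 1 CPM left out, the median of this list turned to -0.37 in the authors' deposited table (adjusted p = 0.0459 against random lists). By its mean over all members, 0.77 in the authors' deposited table, the list did not pass (adjusted p = 0.113 against random lists). PDPN was at 3.35 in D, 1.47 in W, 79.6 in P, 80.8 in M, 81.3 in K, 0.225 in I, 0 in T, 0 in G and 0.11 in S, all in CPM.

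Some markers of other lung cell types also had an FDR under 0.05. Endothelial markers had 4 of 11 positive and 0 negative in the authors' deposited table (7 positive and 0 negative adjusted over the list alone), namely EGFL7 (2.43), TIE1 (5.08), KDR (5.87) and CDH5 (8.09). Its median in the authors' deposited table was 2.10 (adjusted p = 0.000567 against random lists, adjusted p = 0.0738 with an estimated correlation). EGFL7 and TEK were the most abundant of them, at 19.9 ± 14.6 CPM and 14.9 ± 11.0 CPM (SD, n = 9 each). Haematopoietic and immune markers had 3 of 9 positive and 0 negative in the authors' deposited table (3 positive and 0 negative adjusted over the list alone), namely CD14 (2.54), PTPRC (3.73) and CD34 (3.34). Over the whole list the median in the authors' deposited table was 1.49 (adjusted p = 0.0212 against random lists, adjusted p = 0.0738 with an estimated correlation). That median was the value of LYZ (FDR = 0.488), a gene under a mean of 1 CPM. Only 3 of the 9 members had a mean of at least 1 CPM. PTPRC, the CD45 gene, reached 18.5 CPM in W and 18.4 CPM in P. CD34 also belongs to the adventitial list. By its mean, 1.25 in the authors' deposited table, the haematopoietic list did not pass (adjusted p = 0.0730 against random lists). In the authors' deposited table, 1 of 11 epithelial markers was positive and 0 negative (2 positive and 0 negative adjusted over the list alone), CDH1 (3.98), at 0 to 0.450 CPM. The epithelial list did not pass in the authors' deposited table (median -0.35, adjusted p = 0.763 against random lists, adjusted p = 0.403 with an estimated correlation), and its most abundant members were KRT19 at 20.0 ± 19.2 CPM and MUC1 at 5.48 ± 4.18 CPM (SD, n = 9 each).

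Mesothelial markers had 2 of 7 positive and 0 negative in the authors' deposited table (2 positive and 0 negative adjusted over the list alone), WT1 (4.60) and CALB2 (4.07), and did not pass as a list (median 0.99, adjusted p = 0.0507 against random lists, adjusted p = 0.330 with an estimated correlation). Schwann and neural crest markers had 1 of 7 positive and 0 negative in the authors' deposited table (2 positive and 1 negative adjusted over the list alone), ERBB3 (2.63), with a list median of -0.71 (adjusted p = 0.448 against random lists, adjusted p = 0.874 with an estimated correlation). For pericyte markers, the authors' deposited table had 2 of 9 negative and 0 positive (0 positive and 2 negative adjusted over the list alone), CSPG4 (-2.40), which encodes the NG2 proteoglycan, and TRPC6 (-4.01) (list median -0.41, adjusted p = 0.158 against random lists, adjusted p = 0.537 with an estimated correlation). CSPG4 averaged 174 ± 152 CPM (SD, n = 9). None of 14 contractile and smooth muscle genes had an FDR under 0.05 in the authors' deposited table (0 positive and 0 negative adjusted over the list alone too). The list median was 0.84 in the authors' deposited table (adjusted p = 0.000971 against random lists, adjusted p = 0.626 with an estimated correlation). By its mean, 0.60 in the authors' deposited table, the contractile list did not pass (adjusted p = 0.174 against random lists).

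The largest fold changes belonged to genes with few or no counts in several colonies, and such a fitted fold depends on the prior count used. The largest positive values in the authors' deposited table at an FDR under 0.05 and a mean of at least 1 CPM were those of DSG2 (13.32), RFLNA (11.03), SCARA5 (9.29), UNC13A (9.16), PI16 (9.10), PDPN (9.08), CSF2RB (9.01), ENPEP (9.01), GATA4 (8.94), UNC5C (8.79), ADRA2A (8.70), DSG3 (8.65), RGS7BP (8.37), MYH2 (8.33) and MYOZ2 (8.25). Among the largest negative values in the authors' deposited table were those of EYA4 (-7.75), CGA (-7.30), PIWIL3 (-6.66), NCAM1 (-6.19), TBX4 (-5.81), HOPX (-5.25), FMO2 (-5.02), INSC (-5.00), TMSB15A (-4.90), GCNT2 (-4.88), MT1M (-4.82), EML5 (-4.72) and CDCA7 (-4.67). EYA4, which encodes a transcriptional coactivator and phosphatase, was at 0 in D, 0 in W, 0.193 in P, 0.0696 in M, 0.105 in K, 15.9 in I, 24 in T, 26.4 in G and 4.72 in S, all in CPM. MT1M, a metallothionein gene, was at 0.874 in D, 0 in W, 1.29 in P, 0.417 in M, 0.579 in K, 19.8 in I, 16.1 in T, 19.1 in G and 16.9 in S, all in CPM. EML5 overlaps another gene over 53.1% of its exon bases.

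Several of these genes came from 1 colony. DSG2, a desmosomal cadherin (ENSG00000046604.14, chromosome 18, 31498177 to 31549008, GRCh38.p14), had 4882 counts (356 CPM) in colony D and none in the other 8. DSG3, on the same chromosome, had 192 counts (14 CPM) in D and none elsewhere, and GATA4 had 278 counts (17.1 CPM) in W and none elsewhere. Colony K held 698 CPM of PI16, and the next colony, W, held 10.4 CPM. Of all 2533 genes at an FDR under 0.05 in the authors' deposited table, 491 (19.4%) had more than 50% of their summed CPM in 1 colony. Among the 1570 genes at an FDR under 0.05 in the authors' deposited table with a mean of at least 1 CPM, 115 (7.32%) did. Of the 11582 other genes of that level in the authors' deposited table, 120 (1.04%) did so.

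The colonies resembled each other broadly. Over 13152 genes, Pearson r of log2(CPM + 1) between pairs of colonies had a median of 0.91 over 36 pairs, from 0.84 for K and I to 0.97 for P and M; these are correlations across genes, which are not independent replicates. The counts of P and M, the closest pair, still differed by more than counting noise, with a chi-square of 76.8 per gene, so no library was counted as a copy of another. In all, 1380 genes had an SD over the colonies above 1 on the log2 scale, against a median SD of 0.33. With the deposited RPKM, an alternative chosen after seeing the data, 549 genes did. That count used log2(RPKM + 1) over genes with a mean of at least 1 RPKM, so its filter and pseudocount were not alike. The 10 most variable were POSTN (SD 3.98), MFAP5 (SD 3.79), PTGIS (SD 3.72), ITGA11 (SD 3.63), COL4A5 (SD 3.35), SERPINB2 (SD 3.25), TENM3 (SD 3.20), TFPI2 (SD 3.17), ADH1B (SD 3.13) and NFASC (SD 3.13, n = 9 each). ADH1B, an alcohol dehydrogenase gene, was at 1346 CPM in K and 721 CPM in S, and its FDR in the authors' deposited table was 0.902. PTGIS, which encodes prostacyclin synthase, was at 1880.0 CPM in K, and ITGA11, a collagen-binding integrin gene, at 1061 CPM in D. Of the variable genes, 768 (55.7%) had an FDR under 0.05 in the authors' deposited table, against 11.9% of all genes of that level. Both measures come from the same libraries. A gene that differs strongly between the groups also has a high SD, so this excess is built in and is not separate evidence.

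Most gene lists varied more between colonies than genes of like level. Of 32 lists with at least 3 genes at 1 CPM, 26 had a larger median SD than random lists, and 0 a smaller one. Members of a list can vary together over the colonies, which random lists do not reproduce, so p-values of this test can be too small. The inter-gene correlation estimated over the colonies was 0.97 for the cell cycle list and 0.54 for the adventitial list. No test of spread allowed for it, so the 26 lists are not separate findings. The adventitial fibroblast list had a median SD of 2.09 (random lists 0.33), the cell cycle list 1.78 (0.29), the inflammatory list 1.59 (0.35) and the contractile list 1.30 (0.35), each with adjusted p = 0.000640, which comes from the smallest p the random lists can give. The lists that did not pass were the MSC surface markers (adjusted p = 0.0917), epithelial markers (adjusted p = 0.124), osteogenic genes (adjusted p = 0.0514), cholesterol synthesis genes (adjusted p = 0.0841), immediate early and heat shock genes (adjusted p = 0.0856) and mitochondrially encoded genes (adjusted p = 0.108). Each colony was 1 library, so differences between colonies include those of culture and library preparation.

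**Figure D4:**
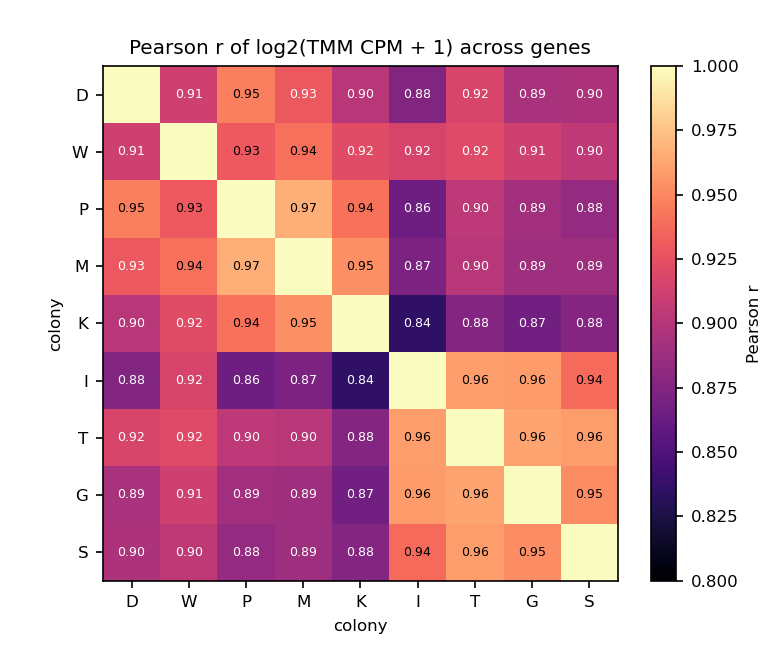
Each cell gives Pearson r across genes of log2(CPM + 1) between a pair of colonies, over genes with a mean of at least 1 CPM. Values run from 0.84 (K and I) to 0.97 (P and M).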

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

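Both tests of a cell source below were chosen after the levels of DSG2 and CDH5 were seen. Of 180 gene levels, list scores and library measures tested over the 9 colonies, 25 had 1 colony far from the other 8. Chance gives about 1 in 20: the same rule picked out 5.10% of simulated sets of 9 normal values and 5.23% of simulated genes with no change between colonies. Most of the values tested were genes named for a large fold change, a small p or a high SD, so their share is not comparable with chance. Over all 13152 genes with a mean of at least 1 CPM the rule picked out 4.90%. The number was 5 in D, 4 in W, 1 in P, 0 in M, 5 in K, 1 in I, 2 in T, 3 in G and 4 in S.

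Colony D stood apart for DSG2 at 356 CPM (next colony 0), DSG3 at 14 CPM (next colony 0), ENPEP at 13.9 CPM (next colony 2.70) and CALB2 at 1.60 CPM (next colony 0.487). DSG2 and DSG3 are genes for desmosomal cadherins. Epithelial cells in the culture would bring their abundant transcripts, but the highest of KRT5, KRT14, EPCAM and CDH1 in colony D was 0.123% of DSG2. KRT19, also expressed in other colonies, was at 14.9 CPM in D and 56.1 CPM in K. The single labelled group gave no biological explanation to test, and differences of donor or culture stay open.

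Colony W stood apart for CDH5 at 22.3 CPM (next colony 1.68), GATA4 at 17.1 CPM (next colony 0), TIE1 at 1.90 CPM (next colony 0.579) and IBSP at 0.737 CPM (next colony 0.0729). CDH5 encodes vascular endothelial cadherin. Endothelial cells would bring PECAM1, VWF and CLDN5, and the highest of these in colony W was 3.03% of CDH5. TEK and EGFL7, endothelial genes present in other colonies too, were at 27.9 and 37.5 CPM in W. Colony W also had the highest scores of the 9 for the endothelial list (1.03, 5 genes) and the haematopoietic list (1.58, 3 genes). It held 12.5 CPM of CD34, 18.5 CPM of PTPRC, 7.98 CPM of CD14 and 10.8 CPM of CSF2RB. Of the 17 haematopoietic and immune markers listed, 9 had a count in any colony. TYROBP, AIF1, C1QA, C1QB, C1QC, MARCO, CD3D and CD3E were not among them. Blood cells as a source were not tested. No biological explanation was tested, and differences of donor or culture stay open.

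Colony K stood apart for PI16 at 698 CPM (next colony 10.4), SCARA5 at 21.1 CPM (next colony 0.307), KDR at 15.1 CPM (next colony 2.19) and EGR3 at 1.79 CPM (next colony 0.583). Its adventitial fibroblast score was 1.71, with the next colony at 0.39. Colony S stood apart for FMO2 at 71.4 CPM (next colony 2.80), NCAM1 at 9.11 CPM (next colony 0.476), HOXD8 at 2.42 CPM (next colony 0) and HOXD4 at 0.403 CPM (next colony 0.0595). Colony G had the lowest THY1, 43.4 CPM beside 388 CPM in the next lowest colony, and the highest TRPC6 (5.06 CPM, next 0.403) and BMP5 (0.491 CPM, next 0). Colony T stood apart for GCNT2 at 10.4 CPM (next colony 0.563) and SOX6 at 1.07 CPM (next colony 0.246), colony P for MYH2 at 9.14 CPM (next colony 2.02), and colony I for FABP4 at 0.845 CPM (next colony 0.329). In colony D the peribronchial fibroblast score was lowest, -0.67 beside -0.13.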

How the results depend on the processing

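The deposited RPKM, the checks on the first principal component and the omission of genes resting on 1 colony were chosen after the data were seen. The counts from the authors' deposited table were 716 positive and 608 negative at an FDR under 0.01, and 900 and 670 among genes with a mean of at least 1 CPM, since both settings leave fewer genes. They were 1285 and 1104 without genes that had over 80% of their summed CPM in 1 colony. Colonies were not left out of that comparison, which was not refitted because its groups are not stated. Of the 19 list calls, 16 kept their call and sign with the 1 CPM filter, 14 with the mean in place of the median and 14 by cameraPR at a preset correlation, a test added after the data were seen. By cameraPR with the estimated correlation 1 was kept, which left 1 positive list and 0 negative. At the preset correlation the progenitor, contractile, alveolar fibroblast, interferon and growth factor lists lost their calls, and the mitochondrial list gained one (adjusted p = 0.00584). With the filter 3 lists were negative: the cell cycle genes, the lung transcription factors (adjusted p = 0.0176) and the progenitor markers, whose median reversed to -0.37 (adjusted p = 0.0459). The chondrogenic (adjusted p = 0.00486) and adipogenic lists (adjusted p = 0.0361) became positive, and the interferon (adjusted p = 0.0769) and growth factor lists (adjusted p = 0.593) lost their calls. With the mean, the progenitor, haematopoietic, contractile, interferon and growth factor lists lost theirs. The cause of these changes was not tested. The median correlation between colonies was 0.97 over all genes with a count and between 0.88 and 0.92 in the other settings. Variable genes numbered 549 with the deposited RPKM, where filter and pseudocount were 1 RPKM and not 1 CPM (the cause was not tested). They numbered 1978 with a pseudocount of 0.1, 1059 with a filter of 5 CPM, and 1311 to 1438 when leaving out each colony in turn. Over the same omissions, lists with a larger spread numbered 25 to 27, and correlated list pairs 2 to 3. The pair added was that of the inflammatory and matrix-degrading scores, with r = 0.94 (n = 8, exact permutation, adjusted p = 0.00357) without colony D, against r = 0.66 (n = 9, exact permutation, adjusted p = 0.236) with it. For spread, the adipogenic list lost its call without D or without P, the haematopoietic list without K and the anterior HOX list without W, while the osteogenic list gained one without W, M, I, G or S and the cholesterol list without K. Depth limits what can be said of genes near 0 CPM.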

Other observations

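The tests of the principal component below were chosen after that separation was seen. Signalling genes went both ways in the authors' deposited table. Of the WNT pathway genes in the authors' deposited table, 4 of 20 were positive and 2 negative (5 positive and 2 negative adjusted over the list alone), with the WNT enhancer RSPO3 (6.56) and the receptor FZD4 (2.14) positive and the transcription factor LEF1 (-4.31) and the antagonist SFRP1 (-3.67) negative. The other positive members in the authors' deposited table, named after their values were seen, were NKD1 (3.54) and SFRP4 (5.70). The WNT list did not pass in the authors' deposited table (median -0.07, adjusted p = 0.631 against random lists, adjusted p = 0.238 with an estimated correlation). SFRP1 was at 1.31 in D, 15.5 in W, 12.9 in P, 3.48 in M, 36.6 in K, 46.6 in I, 58.1 in T, 246 in G and 362 in S, all in CPM. LEF1 had few counts, at 0 to 0.563 CPM. Of secreted growth factors in the authors' deposited table, 5 of 22 were positive and 2 negative (5 positive and 3 negative adjusted over the list alone), among them PDGFD (3.32), VEGFA (2.03), NRG1 (-3.16), FGF5 (-1.65) and, named after their values were seen, VEGFC (1.56) and FGF2 (1.40). The growth factor list passed against random lists in the authors' deposited table (median 0.54, adjusted p = 0.00553 against random lists, adjusted p = 0.270 with an estimated correlation). With genes under a mean of 1 CPM left out, its median in the authors' deposited table was -0.05 (adjusted p = 0.593), and its mean over all members was 0.51 (adjusted p = 0.174), so neither passed. VEGFA averaged 139 ± 121 CPM (SD, n = 9). Among BMP pathway genes in the authors' deposited table, 1 of 15 was positive and 1 negative (1 positive and 2 negative adjusted over the list alone), namely BMP6 (4.92) and BMP5 (-4.22), with median -0.12, adjusted p = 0.448 against random lists, adjusted p = 0.776 with an estimated correlation. BMP5 had counts in colony G alone (0.491 CPM), and BMP6 was at 0 to 26.4 CPM. Of interferon response genes in the authors' deposited table, 1 of 18 was positive and 1 negative (3 positive and 1 negative adjusted over the list alone), BST2 (1.91) and OAS3 (-2.20), with median 0.54, adjusted p = 0.0279 against random lists, adjusted p = 0.599 with an estimated correlation. The interferon call in the authors' deposited table was lost without genes under 1 CPM (median 0.45, adjusted p = 0.0769) and with the mean (0.56, adjusted p = 0.182).

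Lineage genes were mixed. Among chondrogenic genes in the authors' deposited table, 1 of 12 was positive and 2 negative (3 positive and 2 negative adjusted over the list alone): COMP (5.11), a cartilage matrix protein gene, and the transcription factors SOX9 (-2.70) and SOX6 (-3.48), with median 0.01, adjusted p = 0.858 against random lists, adjusted p = 0.825 with an estimated correlation. Without genes under a mean of 1 CPM, the chondrogenic median in the authors' deposited table was 1.84 and passed (adjusted p = 0.00486 against random lists). Among osteogenic genes in the authors' deposited table, 2 of 11 were positive and 0 negative (2 positive and 0 negative adjusted over the list alone), MSX2 (4.60) and IBSP (4.61), with median 0.49, adjusted p = 0.208 against random lists, adjusted p = 0.473 with an estimated correlation. IBSP had few counts, at 0 to 0.737 CPM, and MSX2 was at 0 to 5.28 CPM. Of adipogenic genes in the authors' deposited table, 1 of 11 was positive and 1 negative (1 positive and 1 negative adjusted over the list alone), CD36 (4.02) and FABP4 (-5.56), with median 0.29, adjusted p = 0.361 against random lists, adjusted p = 0.642 with an estimated correlation. FABP4 had few counts, at 0 to 0.845 CPM, and CD36 was at 0 to 5.28 CPM. The adipogenic median in the authors' deposited table was 1.00 and passed with the same filter (adjusted p = 0.0361 against random lists). The alveolar fibroblast and lipofibroblast list in the authors' deposited table had PLIN2 (1.92), a lipid droplet protein gene, and ITGA8 (6.23) positive, so that 2 of 15 were positive and 0 negative (3 positive and 0 negative adjusted over the list alone), with median 0.74, adjusted p = 0.0104 against random lists, adjusted p = 0.403 with an estimated correlation. ITGA8 was at 1.31 in D, 0 in W, 0.129 in P, 1.18 in M, 0 in K, 0 in I, 0 in T, 0 in G and 0 in S, all in CPM. Of peribronchial fibroblast genes in the authors' deposited table, 1 of 9 was positive and 1 negative (1 positive and 2 negative adjusted over the list alone), ASPN (4.36) and DACH2 (-4.36), with median 0.23, adjusted p = 0.703 against random lists, adjusted p = 0.976 with an estimated correlation. For cholesterol synthesis genes in the authors' deposited table, 0 of 15 were positive and 0 negative (0 positive and 0 negative adjusted over the list alone), with median 0.22, adjusted p = 0.301 against random lists, adjusted p = 0.70 with an estimated correlation. For mitochondrially encoded genes in the authors' deposited table, 1 of 13 was positive and 0 negative (1 positive and 0 negative adjusted over the list alone), MT-ND6 (0.85), with median 0.39, adjusted p = 0.254 against random lists, adjusted p = 0.458 with an estimated correlation.

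The first principal component held 45.8% of the variance between colonies. Scores on it were -27.6 for D, -12.6 for W, -51.0 for P, -49.6 for M, -58.2 for K, 66.2 for I, 42.0 for T, 49.3 for G and 41.4 for S, and clustering put D, W, P, M and K apart from I, T, G and S in 15 of 15 settings. The largest gap was 43.5% of the range, and it was 43.5% with every library thinned to the same total, 46.4% without the 100 most abundant genes and 43.6% with trends of GC content and gene length removed, with the same colonies on each side. Totals of D, W, P, M and K lay within the range of the other colonies, so thinning could change little, and depth did not follow the split. Depth and GC or length bias are thus argued against as the whole cause. Leaving out 100 genes can weigh little on the log scale, so it cannot decide on abundant genes. The 10 most abundant genes held 15.6% to 19.8% of counts in D, W, P, M and K and 7.87% to 10.8% in I, T, G and S. The part of this difference was not tested. Batch and donor are not in the labels and stay open, and no biological explanation was tested.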
